A study of Mus musculus with 6 samples.

How the data were processed

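Gene expression was measured in 6 samples of mouse dendritic cells on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample. Per the labels' protocols, bone marrow cells of C57BL/6 mice were grown for 6 days with 10 ng/ml of the growth factor GM-CSF, which yields dendritic cells in culture. Cells carrying the surface proteins CD11c and MHC class II were then sorted by flow cytometry into those with and those without Ly6G, a surface protein typical of neutrophils. Total RNA was extracted with Trizol, and 200 ng was amplified from an oligo-dT primer and labelled with biotin. The labels gave 3 samples of Ly6G+ dendritic cells (Ly6G+ DC) and 3 of Ly6G- dendritic cells (Ly6G- DC), numbered 1 to 3 in each group. The labels do not say that samples of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

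The deposited values were linear signal intensities per probe set, scaled by the authors so that the mean of each array after trimming 2% at either end was 250.0. The submitters' processing notes name Affymetrix Expression Console 2.0, MAS5 and GCOS, and other settings were not given in the sources used here. MAS5 subtracts mismatch signal, which leaves dim probe sets noisy, and scaling to a common mean lets very bright probe sets or a brighter array shift all others. The table held 45101 probe sets, of which 64 were controls for spiked-in or housekeeping transcripts.

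Probe sets were named through the platform's annotation table, in which 34958 had 1 gene symbol, 932 had several and 9211 had none. By Entrez identifier, 34754 matched a RefSeq gene table (assembly GRCm38.p6), and 0 symbols needed an update. No coordinates are given, because no source used here names a genome build for the array. Genes were named only from probe sets with 1 symbol. Ly6g, the gene of the sort marker, was not named in the annotation used, so it could not be checked.

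Signals were analysed as log2(signal + 16) with the authors' scaling kept. This pseudocount understates the fold change of dim genes, and all log2 fold changes are on this scale, as Ly6G+ over Ly6G-. A probe set was kept when its signal lay above that array's 40th percentile on at least 3 of the 6 arrays, whatever their group, which left 28254. A gene was represented by its brightest kept probe set, which gave 13262 genes, 5793 of them with several kept probe sets. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. The fit used the group alone. Errors of log2 fold changes are standard errors (SE) from limma, and errors of signals are SD over 3 arrays. The number of arrays limits the precision.

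The 33 gene lists were fixed before the data were examined and were tested with camera of limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives. Counts of members are given after adjustment over all genes and adjusted over the list alone. Means per list were taken over members centred on their mean of the 6 arrays.

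The rule for named genes, fixed before the data were examined, took up to 12 genes per direction past the threshold with no overlap between groups, up to 4 members past the threshold per list or else its 2 brightest members, and the genes of the sort. Its first part named 0 genes. Further genes were chosen after their values were seen: the 12 genes per direction with the largest log2 fold change among those with an unadjusted p under 0.05, no overlap between groups and a brighter group above the 75th percentile on all its arrays, the genes past the threshold with the hybridization control block, and list members described in the text. Where the dimmer group's mean log2(signal + 16) lay under the mean of its arrays' 40th percentiles on that scale, the fold is given as a bound (at least). The bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the gene's own value and that array's 40th percentile, which is never above the ratio to the percentile alone that the rule had named.

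Arrays were split into 2 sides at the widest gap in the mean log2 signal of the hybridization controls, transcripts spiked into each sample just before hybridization. This split was chosen after seeing the control probe sets, and the sources used here do not say what separates the sides. The split served as a block in limma, as did the array name in the titles, which differs between number 1 and the other numbers, and both together. The other alternatives were quantile normalization, scaling to a common median, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, no intensity trend, a robust variance model, the replicate number as a block, the mean of a gene's probe sets, the exclusion of probe sets with the suffixes _x_at and _s_at, stricter thresholds, lists without the sort genes, and leaving out each array in turn. Control ratios were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1. Means of list members per array were compared between groups with linear models over the 6 arrays and 95% intervals, with the hybridization control side as a block where stated.

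The fit was tested on simulated data for the 13262 genes of this comparison. It recovered 4% of genes changed by a log2 fold of 1, 36% at 2, 70% at 3 and 90% at 4, and called 1 unchanged gene. The simulated noise was independent between genes and arrays, without the hybridization control split. It therefore cannot show how often the real arrays give false calls.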

Results

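Expression was compared between Ly6G+ and Ly6G- dendritic cells with 3 arrays per group. Per the labels, both populations were taken at once from the same GM-CSF bone marrow cultures, but the labels do not say which arrays share a culture, and the fit used the group alone. The comparison asks how dendritic cells that carry a neutrophil surface protein differ in expression from those that do not. Median signals were 69.0, 82.4 and 56.0 on the Ly6G+ arrays and 79.8, 87.4 and 90.8 on the Ly6G- arrays, in numbered order.

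The genes behind the sort were bright in both groups. Signals of Itgax, which encodes CD11c, averaged 5301 ± 2578 in Ly6G+ DC and 7050 ± 2239 in Ly6G- DC (SD, n = 3). The MHC class II genes H2-Ab1 and H2-Eb1 averaged 12870 ± 3163 and 18060 ± 1072 in Ly6G+ DC, against 18870 ± 2422 and 25240 ± 5099 in Ly6G- DC (SD, n = 3). H2-Aa and Cd74, the invariant chain of MHC class II, had log2 fold changes of -1.30 ± 0.74 and -1.02 ± 0.54 (SE). With the hybridization control side as a block they had -0.61 ± 0.26 and -0.63 ± 0.29. Signals of H2-Aa were 14475 to 22344 on the low side and 62040 to 120550 on the high side, across both groups. None of the 5 sort genes passed limma's test of the group alone, and their smallest adjusted p was 0.715. As a list they were lower in Ly6G+ DC (camera of limma, adjusted p = 0.0222), with an adjusted p = 0.31 with an estimated correlation. Means per array overlapped between groups, with Ly6G+ DC 2 at 0.023 and Ly6G- DC 1 at -0.044. The list's adjusted p was 0.0978 without Ly6G+ DC 3 and 0.0596 without Ly6G- DC 3. The cells were selected on these proteins, so the genes check the labels and are no finding.

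Hybridization controls separated the arrays across both groups. Their geometric mean signal was 1989, 8031 and 2530 on the Ly6G+ arrays and 1863, 15350 and 15796 on the Ly6G- arrays, so Ly6G+ DC 2, Ly6G- DC 2 and Ly6G- DC 3 formed the high side. Values within a side therefore rest on 1 array of one group against 2 of the other. The ratio of 3' to 5' signal of Actb was 3.98, 6.85 and 6.55 on those arrays and 1.17 to 1.49 on the others. The log2 ratio averaged 0.94 ± 0.93 in Ly6G+ DC and 1.90 ± 1.46 in Ly6G- DC for Actb, and 0.13 ± 0.60 and 1.05 ± 1.17 for Gapdh (SD, n = 3). An exact two-sided permutation test gave p = 0.4 for each, where 0.1 is the smallest p it allows, so a difference is not excluded. The highest signal was 26674 to 32052 on the low side and 79712 to 138680 on the high side, so the brightest genes followed this split. Arrays correlated across kept probe sets with a mean Pearson's r of 0.901 on the same side and 0.849 on different sides, against 0.873 within and 0.868 between the sorted groups.

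**Figure D1:**
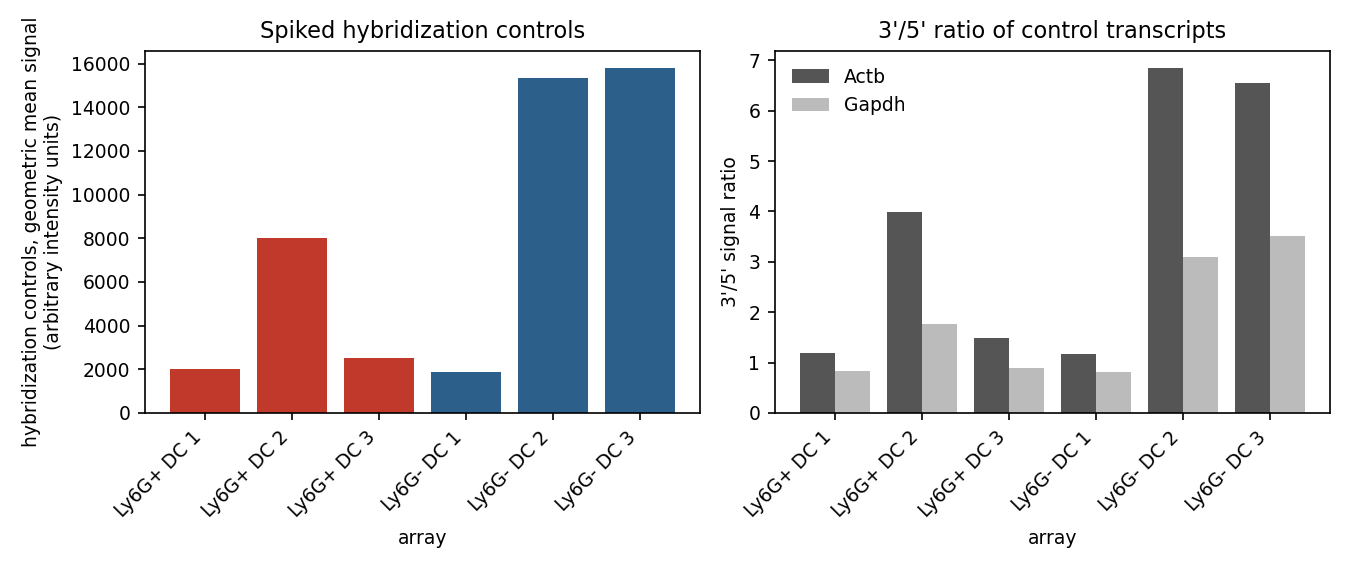
The bars give, for each of the 6 arrays, the geometric mean signal of the hybridization controls in arbitrary intensity units (left; red, Ly6G+ DC; blue, Ly6G- DC) and the ratio of 3' to 5' signal of Actb and Gapdh (right). The 3 arrays with control signals of 8031 to 15796 also have the higher ratios, with Actb at 3.98 to 6.85.

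Genes of neutrophils had the largest differences between the sorted populations. S100a8 and S100a9, which form the calcium-binding protein calprotectin, averaged 25660 ± 4171 and 26460 ± 4114 in Ly6G+ DC and 2662 ± 1862 and 2201 ± 1969 in Ly6G- DC (SD, n = 3). Lcn2, an iron-sequestering granule protein, had a log2 fold change of 4.48 ± 0.65, and Ngp, a granule protein, one of 3.20 ± 0.45 (SE). Lrg1 was at least 7.97-fold higher and Cxcr2, a receptor for neutrophil-attracting chemokines, at least 3.96-fold higher in Ly6G+ DC. Slc2a3, a glucose transporter, Ptgs2, the inducible cyclooxygenase, Prg2, an eosinophil granule protein, and Egr1, an immediate early transcription factor, had log2 fold changes of 2.74 ± 0.39, 2.68 ± 0.48, 2.61 ± 0.52 and 1.66 ± 0.31 (SE). Each of these 10 genes was higher on every Ly6G+ array than on every Ly6G- array. The other kept probe set of Ptgs2 overlapped between groups, with a log2 fold change of 0.56 ± 0.72, and that of Slc2a3 had 2.43 ± 0.37.

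With the fit of the group alone, limma called 0 of 13262 genes (smallest adjusted p = 0.0578) and 0 of 28254 probe sets (smallest adjusted p = 0.165). At an unadjusted p under 0.05 there were 915 genes, 450 higher and 465 lower in Ly6G+ DC, where chance gives 663.1. With each array scaled to a common median they were 557 and 337. Groups did not overlap for 657 higher and 1042 lower genes, together 12.8% of genes where chance gives 10%. With the hybridization control side as a block, limma called 9 genes, all higher in Ly6G+ DC: Lrg1, Lcn2, S100a8, Ngp, Cxcr2, Slc2a3, Ptgs2 and Prg2 at an adjusted p of 0.0373 and Egr1 at 0.0416. Within the low side, the log2 fold changes of Lcn2, S100a8 and Ngp were 4.29, 3.41 and 3.12, and within the high side they were 3.89, 3.55 and 3.10. With the array name as a block there were 19 calls, 18 of them higher, and with both blocks 0. In the fit with both, Ly6G+ DC 3 was alone in its block and added nothing to the group difference. That 0 therefore does not show that the blocks account for the calls. Without Ly6G- DC 1 there were 26 calls, without Ly6G- DC 2 there were 14, and without Ly6G+ DC 2 there was 1. Without Ly6G+ DC 1, Ly6G+ DC 3 or Ly6G- DC 3 there were 0. At an unadjusted p under 0.05 there were 375 genes without Ly6G+ DC 3 and 482 without Ly6G- DC 3. Both counts lie under the 663.1 of chance, so the excess was lost without either of these arrays. Without Ly6G+ DC 1, Ly6G+ DC 2, Ly6G- DC 1 or Ly6G- DC 2 there were 873, 1127, 1938 and 784, all above 663.1.

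Of 25 measured neutrophil markers, 20 were higher in Ly6G+ DC when adjusted over the list alone, 0 over all genes. They included Stfa2l1, a stefin, with a log2 fold change of 4.40 ± 0.64, Padi4, which converts arginine in histones to citrulline, with 2.52 ± 0.58, Csf3r, the receptor for G-CSF, with 2.45 ± 0.51, and Fpr2, a formyl peptide receptor, with 2.07 ± 0.70 (SE). Stfa2l1 was dim in Ly6G- DC: its signals of 36.5 and 18.1 on numbers 1 and 3 lay under those arrays' 40th percentiles of 54.6 and 61.7. Ifitm1 and Alox5ap, the brightest members, had log2 fold changes of -0.84 ± 0.55 and 0.68 ± 0.40 and did not pass. With the hybridization control block they had -0.40 ± 0.23 and 0.47 ± 0.27. The mean of the list was 0.92 ± 0.40 in Ly6G+ DC and -0.92 ± 0.48 in Ly6G- DC on the log2 scale (SD, n = 3), with no overlap. The list was higher by camera of limma (adjusted p = 3.82e-28), with an adjusted p = 0.20 with an estimated correlation. Its median log2 fold change was 1.61, with 1.22 on the low and 1.57 on the high side of the hybridization controls, and 0.99 and 1.99 within the array names. Its camera adjusted p was 4.82e-26 with the hybridization control block, and 0.21 with that block and an estimated correlation.

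Of 19 genes on the list for secondary and tertiary granules of maturing neutrophils, 13 were higher in Ly6G+ DC when adjusted over the list alone and 0 over all genes. Ltf, which encodes lactoferrin, had a log2 fold change of 3.58 ± 0.57 and Mmp9, a gelatinase, one of 3.12 ± 0.51 (SE). Camp, an antimicrobial peptide, was at least 11.0-fold higher, Chil1 at least 6.07-fold and Cd177 at least 3.84-fold. Lyz2 and Mmp8, the brightest members, had log2 fold changes of 0.30 ± 0.51 and 0.59 ± 0.35. The list's median log2 fold change was 1.97 (1.96 on the low and 1.67 on the high side), with a camera adjusted p of 6.47e-21 by limma, 1.54e-20 with the hybridization control block, and an adjusted p = 0.23 with an estimated correlation. Of 9 genes on the primary granule list 1 passed when adjusted over the list alone, Serpinb1a, a protease inhibitor, at least 3.64-fold higher. The granule enzymes Mpo, myeloperoxidase, Elane, neutrophil elastase, and Prtn3, proteinase 3, did not pass. They had log2 fold changes of 0.21 ± 0.39, 0.79 ± 0.64 and -0.47 ± 0.38. Hk3 and Igfbp4, the brightest members of that list, had 0.31 ± 0.43 and -0.62 ± 0.47. The primary granule list had an adjusted p of 0.112 by camera of limma, which was 0.0257 without Ly6G+ DC 3.

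**Figure D2:**
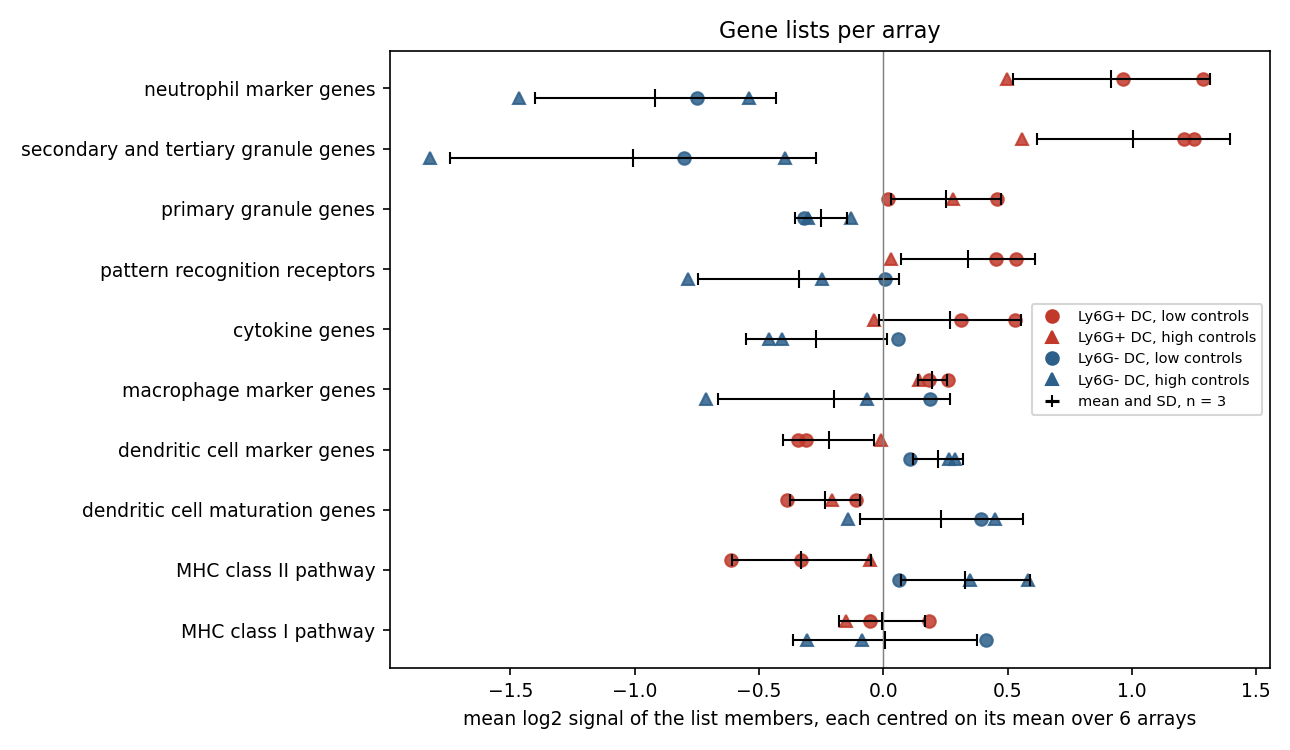
Each point is the mean log2 signal of 1 gene list on 1 array, with every member centred on its mean over the 6 arrays; red marks Ly6G+ DC, blue Ly6G- DC, circles the low and triangles the high side of the hybridization controls, and black bars the mean and SD of 3 arrays. Neutrophil markers lie at 0.92 ± 0.40 in Ly6G+ DC and -0.92 ± 0.48 in Ly6G- DC, and the MHC class II pathway at -0.33 ± 0.28 and 0.33 ± 0.26.

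The lists of the MHC class II pathway, dendritic cell markers and dendritic cell maturation passed camera of limma as lower in Ly6G+ DC, but not with an estimated correlation (adjusted p = 0.30, 0.26 and 0.31). In the MHC class II pathway, 12 of 13 members had negative log2 fold changes, among them H2-DMb2, part of the peptide-loading factor, with -1.21 ± 0.46 and H2-Oa with -0.70 ± 0.30 (SE). The sort genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 are 4 of the 13, and Itgax is 1 of the dendritic cell markers. Without them 8 of 9 MHC class II members and 18 of 23 markers were negative, with camera adjusted p-values of 0.00129 and 6.25e-04, each with an adjusted p = 0.253 with an estimated correlation. Of 24 dendritic cell markers 19 were negative, and Flt3, a receptor for a dendritic cell growth factor, passed when adjusted over the list alone, at least 2.94-fold lower. The transcription factors Irf8, Spib, Batf3 and Zbtb46 had log2 fold changes of -1.01 ± 0.33, -1.20 ± 0.34, -0.93 ± 0.35 and -0.75 ± 0.29, and Id2 and Cd24a, the brightest markers, -0.28 ± 0.56 and -0.06 ± 0.45. Other kept probe sets of Zbtb46 had -0.168, -0.0025 and 0.423. Sirpa, among the 5 markers with positive values, had 0.97 ± 0.46. Of 31 maturation genes 27 were negative, including Ccr7, the receptor that guides dendritic cells to lymph nodes, with -0.98 ± 0.37, Fscn1 with -1.18 ± 0.63, Ccl22 with -0.76 ± 0.40 and Cd83 with -0.74 ± 0.33. With the hybridization control block Fscn1 had -0.62 ± 0.30.

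By camera of limma these lists had adjusted p-values of 1.49e-04 (MHC class II), 4.22e-04 (markers) and 2.22e-05 (maturation). With the hybridization control block they were 1.39e-06, 0.00186 and 2.50e-09, and with that block and an estimated correlation 0.27, 0.23 and 0.36. Means per array did not overlap between groups for the MHC class II and marker lists. They overlapped for maturation, where Ly6G- DC 2 lay at -0.14 and Ly6G+ DC 1 at -0.11. Adjusted over the list alone, 0 MHC class II genes, 1 marker and 0 maturation genes passed, and 0 over all genes. Median log2 fold changes were -0.65, -0.40 and -0.53, with -0.45, -0.63 and -0.60 on the low side and -0.57, -0.36 and -0.45 on the high side. The 17 measured genes of the MHC class I pathway had a median of -0.09 and an adjusted p of 0.898 by camera of limma, with B2m at 0.22 ± 0.36 and H2-D1 at -0.31 ± 0.36. The 19 measured genes of T cell costimulation and inhibition had an adjusted p of 0.121, with 0 members passing when adjusted over the list alone, Arg1 at 0.81 ± 0.43 and Cd274, which encodes PD-L1, at -0.31 ± 0.35. That list's adjusted p was 0.0365 without Ly6G- DC 2.

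The lists of cytokines, chemokines and pattern recognition receptors passed camera of limma as higher in Ly6G+ DC, but not with an estimated correlation (adjusted p = 0.24, 0.26 and 0.24). Of 20 measured cytokines 15 had positive values, and 7 passed as higher when adjusted over the list alone and 0 over all genes, among them Il1a with a log2 fold change of 1.54 ± 0.40, Il6 with 1.62 ± 0.44, Osm with 1.32 ± 0.35 and Tnf with 1.11 ± 0.30 (SE). The interleukin 1 antagonist gene Il1rn passed as well, with 1.39 ± 0.48. Il1b had 2.03 ± 0.79 and did not pass. Of 21 chemokines 3 passed over the list alone, the neutrophil attractants Cxcl2 with 1.57 ± 0.38 and Cxcl3 with 2.16 ± 0.44, and Ccl3 with 1.38 ± 0.37. Ccl6 had 0.23 ± 0.37. Of 23 pattern recognition receptors 4 passed over the list alone, the C-type lectins Clec4d and Clec4e with 1.86 ± 0.51 and 1.58 ± 0.43, and the Toll-like receptors Tlr2 and Tlr7 with 1.27 ± 0.40 and 1.61 ± 0.44. Cd14 and Clec4n had 1.52 ± 0.57 and 0.51 ± 0.35. Camera of limma gave adjusted p-values of 2.22e-05 for cytokines, 0.0295 for chemokines and 5.72e-07 for the receptors. They were 5.07e-05, 0.0578 and 3.09e-06 with the hybridization control block, and 0.21, 0.35 and 0.23 with that block and an estimated correlation. Means per array overlapped between groups for cytokines, where Ly6G+ DC 2 lay at -0.036 and Ly6G- DC 1 at 0.059. The chemokine list had an adjusted p of 0.0703 without Ly6G+ DC 1 and 0.0596 without Ly6G- DC 3.

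Of 17 chemokine receptors, Cxcr2 passed as higher when adjusted over the list alone and 0 over all genes. Ccr1 and Ccr7 did not pass: Ccr1 had a log2 fold change of 1.09 ± 0.46 and Ccr7 one of -0.98 ± 0.37 (SE). Of 20 growth factor receptors 2 were higher over the list alone, Csf3r and the decoy receptor Il1r2 with 1.22 ± 0.37, and 1 was lower, Flt3. Csf2rb, a chain of the GM-CSF receptor, and Csf1r had -0.48 ± 0.53 and -0.08 ± 0.45. The 13 Fc and complement receptor genes had 11 positive values, with Fcgr3 at 0.53 ± 0.31 and Itgb2 at 0.56 ± 0.33, and 0 passed over the list alone. Camera of limma gave adjusted p-values of 0.0107 for chemokine receptors, 2.77e-04 for Fc and complement receptors and 0.0586 for growth factor receptors, and with an estimated correlation adjusted p = 0.24, 0.31 and 0.40. With the hybridization control block they were 0.017, 5.78e-04 and 0.262. Means per array overlapped between groups for Fc and complement receptors, where Ly6G+ DC 2 lay at 0.033 and Ly6G- DC 1 at 0.148. With the array name block the growth factor receptor list passed, with an adjusted p of 0.0354 by camera. The growth factor receptor list had an adjusted p of 0.014 without Ly6G+ DC 2 and 0.0132 without Ly6G- DC 1.

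Markers of other cell types were measured because a sort can hold them. Of 12 monocyte markers Plac8 and Vcan were higher when adjusted over the list alone, with log2 fold changes of 1.63 ± 0.41 and 1.23 ± 0.38, and Fn1 and Emilin2 had 0.75 ± 0.43 and 0.86 ± 0.36 (SE). Of 25 macrophage markers 19 had positive values and 0 passed over the list alone, with Mrc1, the mannose receptor, at 1.47 ± 0.65, Fabp5 at -0.48 ± 0.49 and Csf1r at -0.08 ± 0.45. Of 11 mast cell, basophil and eosinophil markers Prg2 passed over the list alone, while Gata2 had -0.25 ± 0.29. The 8 T and NK lymphocyte markers, 11 B lymphocyte markers and 5 erythroid genes had 0 members passing over the list alone, with Klrd1 at -0.86 ± 0.32, Zap70 at -1.42 ± 0.49, Cd22 at -0.01 ± 0.39, Ms4a1 at -0.75 ± 0.38, Car2 at -0.38 ± 0.30 and Epor at 0.995 ± 0.508. Camera of limma gave adjusted p-values of 2.98e-04 (monocyte), 0.00121 (macrophage), 0.0586 (mast cell, basophil and eosinophil), 0.0212 (T and NK, lower), 0.208 (B) and 0.185 (erythroid). With an estimated correlation they were adjusted p = 0.31, 0.33, 0.30, 0.31, 0.51 and 0.40. Means per array overlapped between groups for the monocyte and macrophage lists. The macrophage list's median log2 fold change was 0.008 on the low and 0.529 on the high side of the hybridization controls. The T and NK list had 0.0564 with the hybridization control block. The T and NK list also missed the threshold without Ly6G+ DC 1 (0.0859) and without Ly6G- DC 3 (0.0945), and the macrophage list without Ly6G- DC 3 (0.113). The mast cell, basophil and eosinophil list had 0.025 without Ly6G+ DC 2, 0.041 without Ly6G- DC 1 and 0.0365 without Ly6G- DC 2. With the array name block it had 0.0422.

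**Figure D3:**
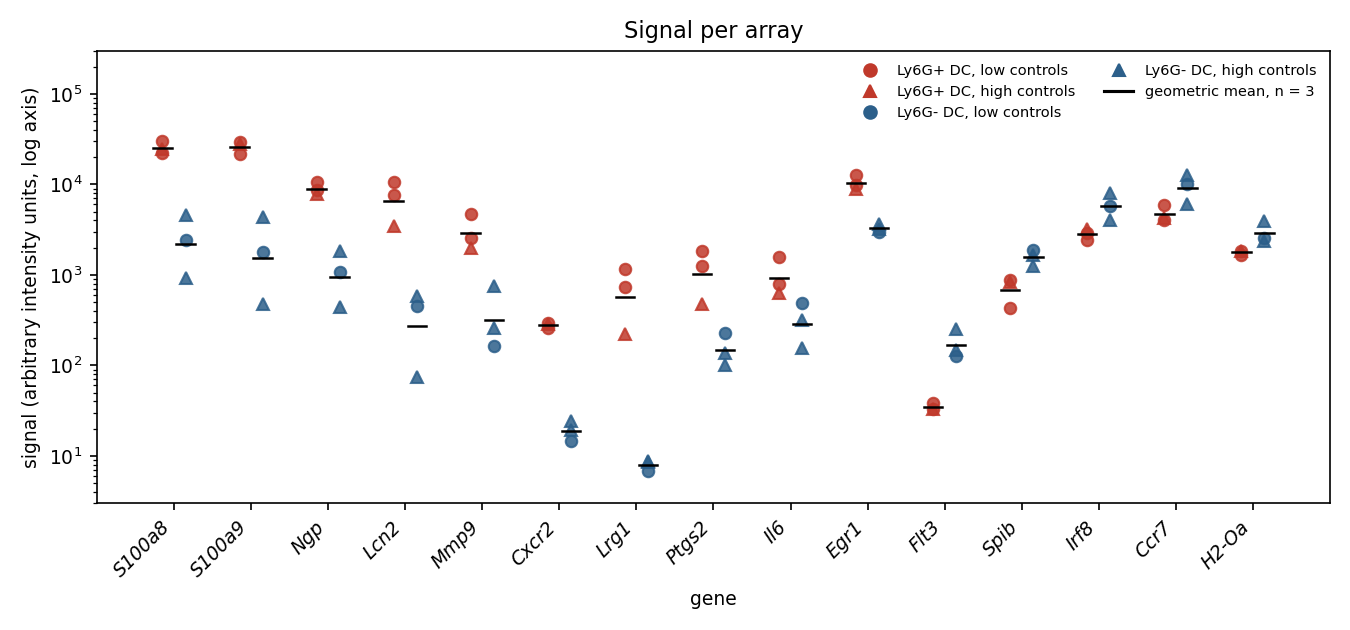
Each point is the signal of 1 gene on 1 array in arbitrary intensity units on a log axis; red marks Ly6G+ DC, blue Ly6G- DC, circles the low and triangles the high side of the hybridization controls, and black lines the geometric mean of 3 arrays. S100a8 has arithmetic means of 25660 in Ly6G+ DC and 2662 in Ly6G- DC, and Spib of 713.6 and 1609.

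Among bright genes that lay lower on every Ly6G+ array, Haao, an enzyme of tryptophan breakdown, had the largest difference, with a log2 fold change of -1.66 ± 0.38 (SE). It averaged 676.0 ± 400.6 in Ly6G+ DC and 1977 ± 352 in Ly6G- DC, and Hs3st2, a heparan sulfate sulfotransferase, 142.7 ± 40.4 and 476.8 ± 167.8 (SD, n = 3). Hdac6, a cytoplasmic deacetylase, Slc9a3r2 and Mmp23 had log2 fold changes of -1.56 ± 0.45, -1.32 ± 0.42 and -1.26 ± 0.33 (SE). Slco2b1, Fbxo36, Nectin2, Ptms and Casp14 had -1.24 ± 0.51, -1.20 ± 0.30, -1.17 ± 0.36, -1.17 ± 0.40 and -1.14 ± 0.33. The other kept probe sets of Hs3st2, Slco2b1, Fbxo36 and Nectin2 had smaller differences of -0.62, -0.58, -0.25 and -0.41. Those of Mmp23 and Ptms had -1.02 and -0.88, and those of Slc9a3r2 -0.69 to -1.50. None passed limma's test over all genes, with adjusted p-values of 0.402 to 0.710. With the array name as a block Haao was the 1 gene called as lower.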

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

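A poly-A spike-in control outside the gene comparison, AFFX-r2-Bs-thr-5_s_at, stood out because its signal was higher on every Ly6G+ array than on every Ly6G- array, with a ratio of means of 4.08. It was 1 of 64 control probe sets to do so, where chance gives 3.2. The 3' probe sets of the poly-A controls varied widely within both groups. Their geometric means were 12.7, 308.5 and 1378.5 on the Ly6G+ arrays and 19.9, 393.8 and 173.9 on the Ly6G- arrays, in numbered order.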

How the results depend on the processing

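The hybridization control block, its combination with the array name, the estimated-correlation tests with a block, and lists without the sort genes were chosen after seeing the data. The count of genes past limma's threshold, 0 in the fit of the group alone, was 2 with quantile normalization, 2 with median scaling, 10 with a pseudocount of 64, 1 without an intensity trend, 2 with the mean of probe sets, 9 with the hybridization control block and 19 with the array name block. It was 0 under the other alternatives that kept all arrays, both blocks together included, apart from the replicate block. With both blocks together, Ly6G+ DC 3 was alone in its block and added nothing to the group difference. Leaving out 1 array gave 0 to 26 genes, 0 to 24 probe sets and 11 to 21 lists, with 11 lists without Ly6G- DC 3. The array name block gave 21 probe sets. The 18 lists past the threshold became 0 with an estimated correlation (smallest adjusted p 0.197), 0 with fry (0.0895), and 0 with an estimated correlation and the hybridization control block (0.214) or the replicate block (0.427). The cause was not tested. The sort genes stayed at 0 calls in all alternatives. With the replicate number as a block there were 20 genes, 19 probe sets and 21 lists. The numbers were not taken as pairs, since no label says that a number marks one culture and the rule asked for a correlation over 0.1 in every pair. Deviations from the group means correlated at 0.52, 0.26 and -0.04 for numbers 1, 2 and 3. Not every sample correlated best with its own number, which leaves pairing open. The arrays of number 3 lie on different sides of the hybridization control split, so their correlation cannot tell a missing pairing from that split. Of 2393 log2 fold changes of 120 named genes, 2253 kept direction and side of the threshold, 86 passed it and 54 changed sign, however small the value. Of 789 list values 644 were the same, 103 lost the call, 33 gained it and 9 changed direction. None of the changed genes and lists passed the threshold with either sign, and the cause was not tested. The sign changed with the hybridization control block for Fdft1 (0.42), Hmgcs1 (0.25), Cd24a (0.18), Id2 (0.18), Cd22 (0.17), Csf1r (0.15), Cox5a (0.082) and Atp5c1 (0.027), and with both blocks for Cd22 (0.27), Csf1r (0.14) and Hmgcs1 (0.0013). With quantile normalization it changed for Csf1r (0.195), Ctss (0.1125), Rps18 (0.1123), Cd22 (0.019) and Rplp0 (0.012), and with median scaling for Cd22 (0.086), Fdft1 (0.064), Cd24a (0.045), Hmgcs1 (0.043) and Csf1r (0.021). With the mean of probe sets it changed for Csf1r (0.35), Hmgcs1 (0.33), Cd24a (0.21), Id2 (0.13), Hspa8 (0.12), Csf2rb (0.048), Pgk1 (0.016) and Fabp5 (0.0075), and without _x_at and _s_at for Pgk1 (0.092), Hspa8 (0.076) and Fdft1 (0.042). Leaving out 1 array gave -0.23 to 0.39 for Cd22, -0.39 to 0.35 for Cd24a, -0.65 to 0.11 for Cox5a, -0.32 to 0.32 for Csf1r, -0.62 to 0.58 for Fdft1, -0.14 to 0.66 for Hk3, -0.43 to 0.33 for Hmgcs1, -0.91 to 0.15 for Id2, -0.053 to 0.69 for Lyz2 and -0.23 to 0.15 for Mcl1. The MHC class I list changed direction with median scaling (adjusted p 0.961), without the filter (0.848), with the mean of probe sets (0.987), without _x_at and _s_at (0.877), without Ly6G- DC 1 (0.185) and without Ly6G+ DC 2 (0.634). Granulocyte transcription factors did so with the mean of probe sets (0.932) and without Ly6G- DC 1 (0.752), and interferon stimulated genes without Ly6G+ DC 1 (0.954). Over all arrays left out, whether or not the direction changed, these 3 lists had adjusted p-values of 0.185 to 0.838, 0.371 to 0.912 and 0.29 to 0.954. Of the named genes, 49 had several kept probe sets and 17 of these had probe sets of opposite sign, H2-DMb2, Zbtb46 and Csf1r among them. Dim genes had noisy signals near the filter, which limits their folds to bounds.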

Other observations

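The lists of immediate early and heat shock, lysosome, glycolysis and cell cycle genes passed camera of limma as higher in Ly6G+ DC, but not with an estimated correlation (adjusted p = 0.20, 0.36, 0.40 and 0.52). Of 21 immediate early and heat shock genes 17 had positive log2 fold changes, and Egr1 passed when adjusted over the list alone, while Fos had 1.11 ± 0.32 and Hspa8 -0.72 ± 0.60 (SE). With the hybridization control block Hspa8 had -0.18 ± 0.24. Of 26 lysosome genes 20 were positive and 0 passed over the list alone, with Ctsl, a cathepsin, at 1.17 ± 0.35, Ctss at -0.42 ± 0.49 and Psap at 0.28 ± 0.39. Of 17 glycolysis genes Slc2a3 passed over the list alone, while Pgk1 and Aldoa had -0.45 ± 0.46 and -0.39 ± 0.44. The 34 cell cycle genes had 24 positive values and 0 passed, with Pcna at 0.98 ± 0.55 and Mcm7 at 0.14 ± 0.27. Camera of limma gave adjusted p-values of 1.49e-04 (stress), 0.013 (lysosome), 0.0455 (glycolysis) and 0.0436 (cell cycle). With the hybridization control block they were 2.26e-05, 0.0196, 0.0461 and 0.00679. Means per array overlapped between groups for the lysosome, glycolysis and cell cycle lists. For cell cycle the highest mean of all arrays was that of Ly6G- DC 2 at 0.445, while Ly6G+ DC 1 lay at -0.281. The lysosome list missed the threshold without Ly6G+ DC 1 (0.172) and without Ly6G- DC 3 (0.10). Glycolysis missed it without Ly6G+ DC 1 (0.24), Ly6G+ DC 2 (0.0656), Ly6G- DC 1 (0.0646) or Ly6G- DC 3 (0.326), and cell cycle without Ly6G+ DC 2 (0.142), Ly6G+ DC 3 (0.406), Ly6G- DC 1 (0.373) or Ly6G- DC 3 (0.305). Glycolysis and cell cycle each lost the call in 13 of 24 alternatives, these included.

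The remaining lists did not pass by camera of limma with the group alone. Adjusted p-values were 0.103 for NADPH oxidase genes, 0.0961 for adhesion molecules, 0.0961 for cholesterol synthesis, 0.121 for oxidative phosphorylation, 0.129 for apoptosis regulators, 0.112 for ribosomal proteins, 0.636 for interferon stimulated genes and 0.636 for granulocyte transcription factors, and 0 members of each passed over the list alone. Among the brightest members, Mx1 and Bst2, which are induced by interferon, had log2 fold changes of -0.84 ± 0.27 and -1.14 ± 0.42, and Cebpb and Xbp1, transcription factors, 0.77 ± 0.36 and -0.68 ± 0.42 (SE). Gpx1, Cyba, Selplg, Hmgcs1, Fdft1, Cox5a, Atp5c1, Mcl1, Bcl2l11, Rplp0 and Rps18 lay between -0.58 ± 0.43 and 0.47 ± 0.43. Of these, Hmgcs1, Fdft1, Cox5a, Atp5c1, Mcl1, Rplp0 and Rps18 changed sign under some alternatives. By camera, cholesterol synthesis had an adjusted p of 0.045 with the hybridization control block, and ribosomal proteins had 0.0264 with the array name block. Leaving out 1 array brought adhesion molecules to 0.0458 (Ly6G+ DC 2) and 0.00974 (Ly6G- DC 1), cholesterol synthesis to 0.0193 (Ly6G+ DC 1) and 0.0172 (Ly6G- DC 2), oxidative phosphorylation to 0.0445 (Ly6G+ DC 1), and ribosomal proteins to 0.0196 (Ly6G+ DC 2) and 0.0085 (Ly6G- DC 1).

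All tests of explanations in this part, the splits of the arrays included, were written after the results were seen. The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real one gave 0 genes and 0 probe sets, which all 10 reach by construction, so this says nothing about chance. The highest other gave 651 genes and 1913 probe sets. That split followed the hybridization controls, which points to a structure of the samples, and with it as a block the real comparison had 9 genes. At an unadjusted p under 0.05 by limma, the real split gave 915 genes and the split along the hybridization controls 3016. The split of Ly6G+ DC 1, Ly6G- DC 1 and Ly6G- DC 3 against the others gave 1056, so 915 did not exceed all other splits. For lists 2 splits gave at least the real 18, with 20 as the highest other. Camera with the preset correlation gave the neutrophil marker list an adjusted p of 3.82e-28 in the real split. In the other splits that value ranged from 1.4e-13 to 0.68.

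The neutrophil marker list and the list of secondary and tertiary granule genes, 44 genes in all, passed camera as higher in Ly6G+ DC but not with an estimated correlation (adjusted p = 0.20 and 0.23), and the primary granule list did not pass (0.112). With the hybridization control side as a block, the mean of the 44 differed by a log2 value of 1.76 (95% interval over the arrays 0.41 to 3.11), and the 25 members above the 75th percentile on every Ly6G- array differed by 1.29 (0.23 to 2.35). Both intervals lie above 0, but not above the 0.5 set as the bound, so neither a batch along that split nor noise of dim probe sets is excluded as part of the pattern. Neutrophils mixed into the Ly6G+ gate stay open, although the gate required CD11c and MHC class II: the median MHC class II signal lay 36.2% lower (27.6 to 42.5, a bootstrap over genes only), and cells that carry both programmes could give the same values. Over the arrays, the mean of the MHC class II list differed by -0.661 (95% interval -1.27 to -0.0505). Its difference minus that of the other dendritic cell lists was -0.206 (-0.705 to 0.293), an interval that includes 0. S100a8 and S100a9, abundant neutrophil transcripts, averaged 25660 and 26460 in Ly6G+ DC, and of the 25 neutrophil markers 15 lay above the 75th percentile on every Ly6G- array and 8 are also held by another list.

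The MHC class II, dendritic cell marker and maturation lists, 67 genes in all, passed camera as lower in Ly6G+ DC but not with an estimated correlation (adjusted p = 0.30, 0.26 and 0.31), and of single genes Flt3 passed over its list and 0 over all genes. With the hybridization control side as a block, the mean of the 67 differed by -0.453 (95% interval over the arrays -0.888 to -0.0178), which does not reach the bound of -0.25 set for excluding a batch along that split. The mean of the 67 minus the median of all genes differed by -0.414 (-0.694 to -0.134), below the bound of -0.1 with its whole interval, and that median itself by -0.0813 (-0.211 to 0.0481). The 67 genes come from lists taken because camera, which sets a list against the other genes, had put them lower. Their difference from the median of all genes repeats that choice, so it is no separate test of an equal shift by the authors' scaling. It also cannot address a shift that depends on brightness, because the median covers genes of all signals. The difference from the MHC class I pathway alone was -0.482 (-1.21 to 0.246), an interval that includes 0. Of the bright ribosomal protein genes 17 of 19 were negative as well. A lower share of dendritic cells through mixing and lower expression in Ly6G+ dendritic cells stay open as hypotheses.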
